A study of Mus musculus with 16 samples.

How the data were processed

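Bulk RNA sequencing had been done on 16 libraries of lamina propria cells of mouse colon and ileum, isolated on a 40% and 80% Percoll gradient from mice born germ-free that had been given either strain of *B. breve* 5 weeks before. The 4 groups of tissue and strain held 4 libraries each. The deposited table held estimated counts per gene, which the authors had made with cutadapt 5.0 and Salmon 1.4.0 against GRCm39, per the submitters' processing notes. It listed 35647 Ensembl gene identifiers, of which 35105 had a symbol. The 542 without one took between 0.0853 and 0.105% of the counts of a library. Between 34.8 and 40.7% of the values of a library were not whole numbers, as Salmon estimates are, and they were rounded to whole counts here. Genomic positions were not used here. Totals per library are totals of estimated counts.

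Each library was assigned to its group by its title. No library was left out. No 2 libraries were copies of each other, with chi-square per degree of freedom between 25.4 and 93.4 for pairs of replicates. Libraries of colon and ileum with the same strain and replicate number were taken as the same mouse, as the design states 4 mice per group. The numbers do not pair mice across strains, so a block for the replicate number in a strain comparison groups mice that the design does not pair.

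Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, libraries were scaled by TMM, and a robust quasi-likelihood fit gave 2-sided tests with Benjamini-Hochberg adjustment over all genes tested, called at an adjusted p under 0.05. The strain was compared in colon and in ileum, each in a fit of 8 libraries. The difference of the strain effect between tissues and the comparison of ileum with colon in each strain came from 1 fit over 16 libraries. CPM of a gene are scaled within the fit they stand beside. The log2 CPM behind list tests, list means and covariate scores have a prior count of 2. Log2 fold changes of genes come from the fit, in which that value was not used. The median log2 fold change of all genes was 0.01 in colon and 0.01 in ileum.

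Gene lists of cell types, pathways and tissue contaminants were fixed before the data were examined, as were the comparisons, the named genes and most alternatives. A list was tested where at least 5 members were, which gave 30 lists. The lists of exocrine pancreas and of sex-linked genes had fewer tested members and were not tested as lists. Lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 between genes and, as an alternative, the correlation estimated for each list, and with fry. Calls over all genes are given beside calls adjusted over the list alone. Symbols in the lists that the table did not hold were left out.

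The rule for named genes took up to 12 rising and 12 falling genes by smallest p among those called with at least 5 CPM in the higher group. It left out variable, diversity and joining segments of immunoglobulins and T cell receptors, gene models without a proper name, pseudogenes and genes with no symbol. With fewer than 10 called, the 10 smallest p values were taken and reported as not passing. From each list described, up to 4 called members were taken or, with none called, up to 3 with the highest mean expression. Members of the acetylcholine list with at least 1 CPM on average in a tissue were named too, and up to 8 genes in each direction for the tissue comparisons and the difference between tissues. Genes outside the rule are named only where it is said that they were chosen after their values were seen. In colon, 1 gene that the rule takes is not reported here.

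The alternatives changed 1 choice at a time. They were RLE size factors, no filter on low counts, a stricter filter of 1 CPM, DESeq2 1.42.0, limma-voom with quality weights, the removal of immunoglobulin genes before normalization, an epithelial score as a covariate, a block for the mouse or the replicate number, 1 fit over all libraries for the strain comparisons, and each library or mouse left out in turn. After the data had been seen, a stromal score as a covariate, the removal of the epithelium-rich colon library from the comparisons between tissues, and an exact permutation test of list values per library were added. A change of pseudocount was planned for normalized values alone and was not run, since the values were counts. A fit with a covariate drawn from the structure of the colon libraries themselves was tried and left out, because that covariate came from the data it would correct.

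Immunoglobulin genes, 425 in the table, were summed per library as a share of all counts, and groups were compared by exact 2-sided permutation tests, of which the smallest p for 4 against 4 libraries is 0.0286. The fits were tested on simulated counts, drawn for each gene apart with its mean and dispersion in the real table. In them 200 genes were changed, and 20 more were shifted by a log2 value of 0.5. These counts held no correlation between genes and no structure of the libraries, so recovery in the real libraries may be lower. Genes changed 2-fold were recovered in 62.2% of cases in colon, 79.4% in ileum and 51.1% in the difference between tissues, and genes changed 4-fold in 95.1%, 92.9% and 91.5%. False calls numbered 9 of 169 calls in colon, 18 of 193 in ileum and 6 of 152 in the difference between tissues. In ileum that was above the share of 0.05 at which the threshold was set.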

Results

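RNA was sequenced from 16 libraries of lamina propria cells of the mouse gut, the mixed immune cells that lie under the intestinal epithelium, enriched on a Percoll density gradient. Germ-free mice had carried a single bacterium for 5 weeks, either wild-type (WT) *Bifidobacterium breve*, a gut commensal, or a Δchat strain that makes no acetylcholine. Each strain was given to 4 mice, and colon and ileum were both taken, so that each of the 4 groups held 4 libraries. The totals of estimated counts ran from 15.9 to 23.6 M (M, mega) per library. Group means (± SD, n = 4) were 20.3 ± 3.01 M in colon WT, 20.7 ± 1.38 M in colon Δchat, 20.2 ± 2.53 M in ileum WT and 20.4 ± 3.56 M in ileum Δchat, and differed by less than the spread between libraries. Between 17261 and 18209 genes had a count in a library. Fold changes are given on the log2 scale with their standard error from the edgeR quasi-likelihood fit, expression is given in CPM (counts scaled to a library of 1 M; mean ± SD, n = 4 libraries per group), and adjusted p values of genes are Benjamini-Hochberg values from edgeR unless another tool is named.

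The strain comparison asks how bacterial acetylcholine acts on immune cells of the gut mucosa, and the acetylcholine genes of the host were looked at first. In colon, *Chrm2* (ENSMUSG00000045613), a muscarinic acetylcholine receptor, stood at 3.76 ± 1.28 CPM in mice with WT *B. breve* and at 8.24 ± 1.44 CPM in mice with the Δchat strain. Its log2 fold change of 1.13 ± 0.27 did not pass over all genes (adjusted p = 0.260) and passed when adjusted over the list alone (adjusted p = 0.0247). *Chrnb1*, a nicotinic receptor subunit, had a log2 fold change of -0.30 ± 0.12 (adjusted p = 0.352), and *Chrnb2*, another subunit, one of 0.01 ± 0.21 (adjusted p = 0.989). In ileum, the values were 0.28 ± 0.35 for *Chrm2* (adjusted p = 0.799), -0.20 ± 0.12 for *Chrnb1* (adjusted p = 0.583) and 0.27 ± 0.27 for *Chrnb2* (adjusted p = 0.742). *Chat*, the enzyme that makes acetylcholine, was too low to be tested in either tissue. Of the acetylcholine list, 11 members were tested in colon and 12 in ileum. None was called over all genes, and 1 in colon and 0 in ileum were called when adjusted over the list alone. The list's median log2 fold change was -0.02 in colon and -0.04 in ileum, and its camera adjusted p was 0.829 and 0.451. By fry in either direction, its adjusted p was 2.5e-04 in colon and 0.420 in ileum.

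In colon, genes of antibody-secreting cells, B cells and macrophages differed by strain as lists. Immunoglobulin genes took 8.90 ± 2.48% of all counts in colon WT and 4.16 ± 0.57% in colon Δchat, with no overlap between the 4 libraries of each group (exact p = 0.0286, Benjamini-Hochberg 0.1). The list of plasma cell genes was lower by camera (adjusted p = 7.6e-18; adjusted p = 0.488 with an estimated correlation). So was that of B cells and of the germinal centre, where B cells mature, while macrophage genes were higher (adjusted p = 1.2e-10 and 5.6e-06; adjusted p = 0.491 each with an estimated correlation). *Retnla* (ENSMUSG00000061100), a secreted resistin-like protein of alternatively activated macrophages and eosinophils, rose 3.29-fold. Epithelial transcripts were higher too, above all in 1 library, Δchat replicate 3.

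*Retnla* was the 1 gene of 14660 tested in colon that passed, with a log2 fold change of 1.72 ± 0.14 (adjusted p = 0.00875), from 9.13 ± 0.30 CPM in colon WT to 30.1 ± 5.59 CPM in colon Δchat. The next smallest p values belonged to genes that did not pass, each at an adjusted p of 0.135. Several of them are B cell genes. *Rgs13*, a regulator of G protein signalling found in germinal centre B cells, stood at 6.49 ± 3.87 CPM in colon WT and 0.593 ± 0.246 CPM in colon Δchat (log2 fold change -3.45 ± 0.50). *Nuggc*, a nuclear GTPase of germinal centre B cells, had a value of -1.65 ± 0.23, *Eaf2* one of -1.27 ± 0.16, and *Mzb1*, a chaperone for antibody secretion, one of -1.03 ± 0.16. *St6gal1*, a sialyltransferase, had a value of -0.87 ± 0.13, and *Manea*, an enzyme of N-glycan trimming, one of -0.81 ± 0.12. The myeloid genes *Ccl6*, a chemokine, and *Alox5ap*, which leukotriene synthesis needs, had values of 1.09 ± 0.16 and 0.79 ± 0.11.

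Beside the 1 call, 1951 genes of colon had an unadjusted p below 0.05 where 733 would be reached by chance, 1172 of them higher and 779 lower with Δchat. DESeq2 called 313 genes, 137 higher and 176 lower, and limma-voom with quality weights called 1. *Retnla* was not past the threshold without Δchat replicate 1 (adjusted p = 0.0703), WT replicate 2 (0.0968) or WT replicate 3 (0.0861), or in a fit over both tissues (0.143). Nor was it with the replicate number as a block (0.0875), which groups mice of both strains that the design does not pair. Over all 18 alternatives its adjusted p ran from 9.7e-22 to 0.143 and its log2 fold change from 1.58 to 1.85.

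Plasma cell and IgA genes formed the list with the smallest camera p in colon. All but 1 of its 27 tested members were lower with Δchat, with a median log2 fold change of -0.65 (adjusted p = 7.6e-18). The call was lost at adjusted p = 0.488 with an estimated correlation, and limma fry gave an adjusted p of 0.0384. No member was called over all genes, and 19 were called lower when adjusted over the list alone. *Igha* (ENSMUSG00000095079), the heavy chain of IgA, had a log2 fold change of -1.25 ± 0.24 (adjusted p = 0.174), *Jchain*, which joins IgA dimers, -1.20 ± 0.23 (adjusted p = 0.173) and *Igkc*, the kappa light chain, -1.16 ± 0.23 (adjusted p = 0.204). The unfolded protein response list, which serves secretory cells, had a median of -0.26 over 26 members (adjusted p = 4.1e-07; adjusted p = 0.491 with an estimated correlation), 9 of them lower when adjusted over the list alone. B cell and germinal centre genes had a median of -0.48 over 26 members (adjusted p = 1.2e-10; adjusted p = 0.491 with an estimated correlation), 5 of them lower when adjusted over the list alone. The most abundant of these were *Ighm*, the heavy chain of IgM (-0.49 ± 0.27), *Cd79a*, a part of the B cell receptor (-0.56 ± 0.21), and *Pax5*, the B cell identity factor (-0.40 ± 0.26), none of which passed. The camera call of the B cell list ended with the epithelial score as a covariate (median -0.09, adjusted p = 0.149); over its 13 alternatives other than the estimated correlation, the adjusted p ran from 1.5e-12 to that value. Without WT replicate 1 its median was -0.30.

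**Figure D1:**
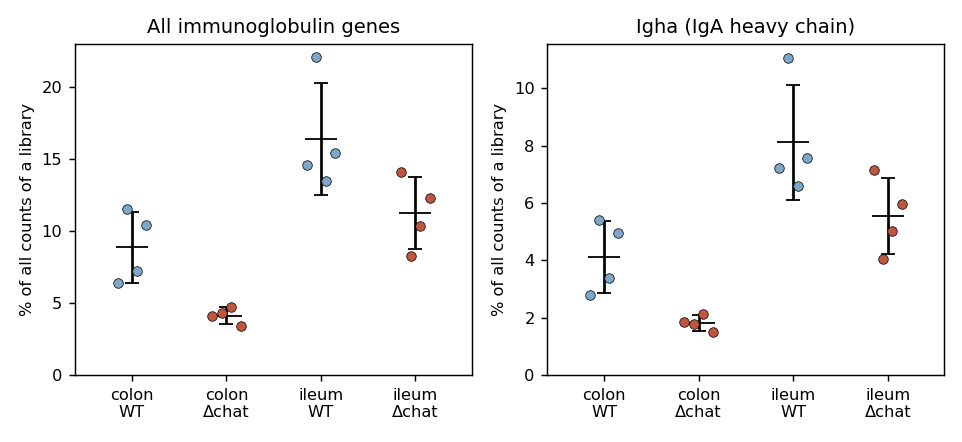
Share of all counts of a library taken by immunoglobulin genes (left) and by Igha alone (right), in percent, with 1 point per library and the mean and SD of the 4 libraries of each group. In colon the 4 Δchat libraries lay between 3.42 and 4.77% and the 4 WT libraries between 6.39 and 11.5%, while in ileum the ranges of 8.31 to 14.1% and 13.5 to 22.1% overlapped.

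Immunoglobulin shares were compared by exact permutation tests over 14 measures, which were chosen after the data had been seen. In colon, the share of all immunoglobulin genes and that of *Igha* (4.13 ± 1.25% against 1.83 ± 0.27%) each gave a two-sided exact p of 0.0286, the smallest that 4 against 4 libraries allow, and a Benjamini-Hochberg value of 0.1. In ileum, all immunoglobulin genes took 16.4 ± 3.87% of counts in WT and 11.3 ± 2.51% in Δchat, and *Igha* took 8.11 ± 2.01% and 5.55 ± 1.33% (two-sided exact p = 0.0571 each, Benjamini-Hochberg 0.133). *Igha* made up 93.6 ± 2.61% of heavy chain constant region counts in colon WT and 89.7 ± 3.82% in colon Δchat (exact p = 0.143), and 98.4 ± 0.72% and 97.9 ± 0.49% in ileum (exact p = 0.229).

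Macrophage genes had a median log2 fold change of 0.64 over 21 tested members in colon (camera adjusted p = 5.6e-06; adjusted p = 0.491 with an estimated correlation), and 11 of them were higher when adjusted over the list alone. The 3 most abundant members were *Apoe*, a lipid carrier (0.48 ± 0.21), *Ctsb* (0.20 ± 0.16) and *Lgmn* (0.04 ± 0.14), the latter both lysosomal proteases, and none passed. Pattern recognition receptors had a median of 0.26 over 27 members, 22 higher and 5 lower (adjusted p = 3.9e-04, or 0.491 with an estimated correlation). Among the most abundant, the adaptor *Myd88* had a value of 0.23 ± 0.09. *Ddx58* went the other way, at 48.1 to 60.8 CPM in Δchat and 59.9 to 72.2 CPM in WT, scaled over the 16 libraries. Immediate early and heat shock genes, which respond to stimulation and to stress, were higher in 29 of 30 members, with a median of 0.33 (adjusted p = 2.9e-06; adjusted p = 0.491 with an estimated correlation), *Junb* at 0.31 ± 0.10 among them. Mast cell, eosinophil and basophil genes had a median of 0.48 over 19 members (adjusted p = 0.00402; adjusted p = 0.491 with an estimated correlation), with 4 higher and 1 lower when adjusted over the list alone, and *Kit*, a mast cell receptor, at 0.40 ± 0.14. Cytotoxic and Th1 genes had a median of 0.24 over 19 members, 15 higher and 4 lower, with the same adjusted p values of 0.00402 and, with an estimated correlation, 0.491. *Klrk1*, an activating receptor of natural killer cells, stood at 0.55 ± 0.17. The more abundant *Stat4* was not higher, at 38.6 to 65.6 CPM in Δchat and 49.9 to 114 CPM in WT, scaled over the 16 libraries. Glycolysis and hypoxia genes had a median of 0.15 over 26 members (adjusted p = 4.5e-04; adjusted p = 0.491 with an estimated correlation), with *Ldha*, lactate dehydrogenase, at 0.22 ± 0.12. No member of these 6 lists was called over all genes. With the epithelial score as a covariate, the mast cell list (adjusted p = 0.0850) and the glycolysis list (adjusted p = 0.342) were no longer called, and the cytotoxic list was not called without Δchat replicate 2 (adjusted p = 0.0591). The lowest adjusted p values of these 3 lists over their 13 alternatives were 6.4e-07, 1.2e-04 and 1.7e-04. Without Δchat replicate 2, the medians were 0.39 for macrophages, 0.17 for pattern recognition receptors and 0.15 for cytotoxic genes. That of the mast cell list was 0.28 without Δchat replicate 1 and 0.74 without Δchat replicate 4, and that of immediate early and heat shock genes was 0.18 without Δchat replicate 4.

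Epithelial carry-over moved with the strain in colon. The general epithelial list had a median of 3.12 over 21 tested members (adjusted p = 1.2e-08; adjusted p = 0.491 with an estimated correlation), 18 of them higher when adjusted over the list alone. The secretory epithelium list had a median of 1.85 over 15 members (adjusted p = 8.0e-05; adjusted p = 0.491 with an estimated correlation) and the colonic epithelium list one of 2.06 over 16 members (adjusted p = 0.00111; adjusted p = 0.661 with an estimated correlation). Without Δchat replicate 3, the medians of the general, secretory and colonic epithelium lists were 1.06, 0.58 and 0.52. With the epithelial score as a covariate they were 0.0225, 0.24 and -0.21, with none called. The keratin *Krt8* stood at 30.0 ± 22.7 CPM in colon WT and at 344 ± 544 CPM in colon Δchat (3.52 ± 1.22, adjusted p = 0.334), and the mucin *Muc2* had a log2 fold change of 3.23 ± 0.88 (adjusted p = 0.313). Over the 16 libraries, the mean log2 CPM of the epithelial list was 2.43 ± 0.81 in colon WT, 4.48 ± 1.66 in colon Δchat, 2.61 ± 1.03 in ileum WT and 3.33 ± 1.24 in ileum Δchat. Stromal and smooth muscle genes had a mean of 7.98 ± 0.48 in colon WT and 7.99 ± 0.21 in colon Δchat. *Cela1*, the 1 tested gene of the exocrine pancreas list, had a value of 3.22 ± 1.16 (adjusted p = 0.335).

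**Figure D2:**
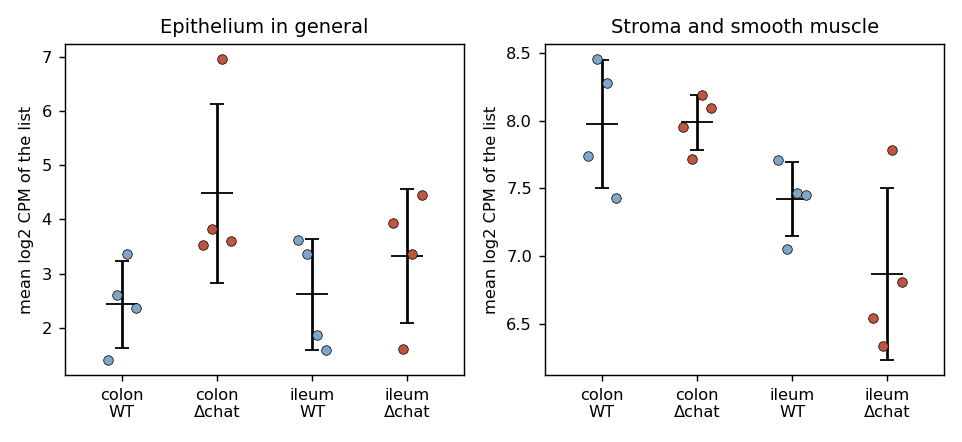
Mean log2 CPM per library of the general epithelial list (left) and of the stroma and smooth muscle list (right), scaled over the 16 libraries, with 1 point per library and the mean and SD of the 4 libraries of each group. The highest epithelial value, 6.96, belongs to colon Δchat replicate 3, and ileum Δchat libraries reach from 6.34 to 7.78 on the stromal scale.

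The 18 lists not called in colon had camera adjusted p values from 0.0529 to 0.987 and medians from -0.10 to 0.77. They included T cells, Th17 cells, regulatory T cells, type 2 lymphocytes, interferon response and inflammatory cytokines. Dendritic cell genes went both ways, with 6 higher and 2 lower when adjusted over the list alone. The median of monocyte and neutrophil genes was -0.03 while the test pointed up. Of the 12 lists called, 0 kept an adjusted p below the threshold with an estimated correlation, and fry called 1 list by direction and 12 in either direction. The mean list value per library gave a two-sided exact permutation p of 0.0286 for 6 of the 30 lists, with 0 past the threshold after adjustment. The plasma cell list was 1 of these, at 7.11 ± 0.16 in WT and 6.40 ± 0.17 in Δchat.

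In ileum, 3 genes passed, all lower with Δchat *B. breve*. *Alox15* (ENSMUSG00000018924), a lipoxygenase of eosinophils and resident macrophages, fell 8.99-fold. *Il1a* (ENSMUSG00000027399), an inflammatory cytokine, fell 4.35-fold, and *Wnt11* (ENSMUSG00000015957), a secreted Wnt ligand, fell 3.07-fold. Plasma cell, unfolded protein response and inflammatory genes were lower as lists by camera (adjusted p = 1.3e-09, 1.3e-09 and 5.9e-05; adjusted p = 0.472 each with an estimated correlation).

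The 3 genes were those that passed of 14496 tested, each at an adjusted p of 0.0498. *Alox15* went from 19.6 ± 7.61 CPM in ileum WT to 2.18 ± 0.31 CPM in ileum Δchat (log2 fold change -3.17 ± 0.34), *Il1a* from 48.9 ± 14.1 to 11.2 ± 2.21 CPM (-2.12 ± 0.23) and *Wnt11* from 13.2 ± 1.64 to 4.29 ± 0.83 CPM (-1.62 ± 0.17). The next genes did not pass. *Mmp25*, a membrane-bound metalloproteinase of neutrophils, stood at 22.9 ± 6.0006 and 6.76 ± 0.70 CPM (-1.76 ± 0.20, adjusted p = 0.0542). At an adjusted p of 0.0739 each, *F5*, coagulation factor V, had a log2 fold change of -1.75 ± 0.23, *Dio2*, a thyroid hormone deiodinase, -4.13 ± 0.57, *Basp1* -0.77 ± 0.10, *Chid1* -0.73 ± 0.10 and *Dusp8*, a phosphatase of MAP kinases, -0.61 ± 0.09. *Ciart*, a repressor of the circadian clock, was the 1 higher gene among the 10, at 21.3 ± 2.06 and 47.3 ± 9.79 CPM (1.15 ± 0.15). *Retnla* had a value of -1.36 ± 0.65 in ileum (adjusted p = 0.494).

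Beside the 3 calls, 1581 genes of ileum had an unadjusted p below 0.05 where 724.8 would be reached by chance, 697 higher and 884 lower. DESeq2 called 374 genes, 131 higher and 243 lower, and limma-voom with quality weights called 164. The number called was 0 without Δchat replicate 1, Δchat replicate 4, WT replicate 1, WT replicate 2 or WT replicate 3, and was 7 without Δchat replicate 2, 11 without WT replicate 4 and 247 without Δchat replicate 3. It was also 0 with RLE size factors, a stricter filter, or an epithelial or stromal covariate, while the log2 fold changes stayed between -3.42 and -3.00 for *Alox15*, -2.28 and -1.98 for *Il1a*, and -1.70 and -1.49 for *Wnt11* in all 18 alternatives, with adjusted p values of up to 0.241.

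**Figure D3:**
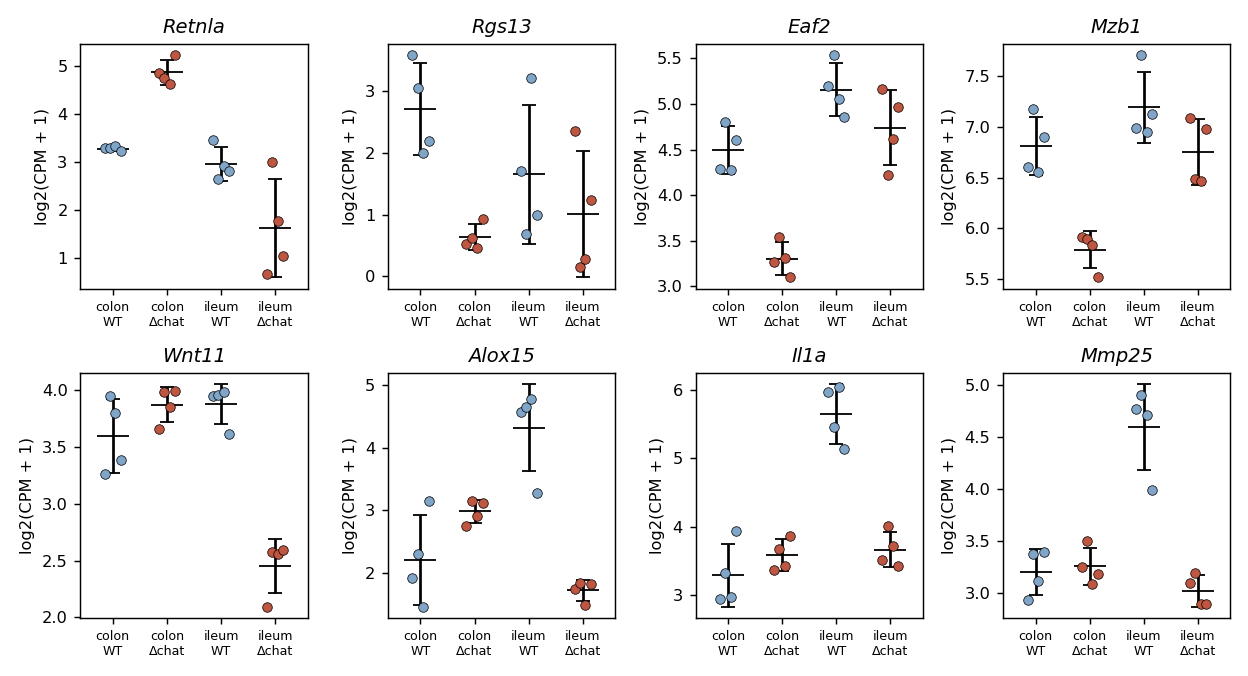
Expression of 8 genes as log2(CPM + 1), scaled over the 16 libraries, with 1 point per library and the mean and SD of the 4 libraries of each group. *Retnla* lay between 23.9 and 36.5 CPM in the colon Δchat libraries and between 8.35 and 9.07 CPM in the colon WT libraries, and *Il1a* lay between 9.77 and 15.2 CPM in the ileum Δchat libraries and between 34.05 and 64.8 CPM in the ileum WT libraries.

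Plasma cell and IgA genes had a median log2 fold change of -0.43 over 27 members in ileum (camera adjusted p = 1.3e-09; adjusted p = 0.472 with an estimated correlation), with 25 lower and 9 of them lower when adjusted over the list alone. *Igha* had a value of -0.67 ± 0.25 (adjusted p = 0.371), *Igkc* -0.69 ± 0.23 and *Jchain* -0.62 ± 0.23. Unfolded protein response genes had a median of -0.24 over 26 members, with the same adjusted p values of 1.3e-09 and, with an estimated correlation, 0.472, and 9 were lower when adjusted over the list alone, among them the chaperone *Hsp90b1* (-0.42 ± 0.10). Inflammatory cytokines and NF-kB targets were lower in 25 of 29 members, with a median of -0.20 (adjusted p = 5.9e-05; adjusted p = 0.472 with an estimated correlation), *Il1a* called over all genes and 5 lower when adjusted over the list alone. Monocyte and neutrophil genes had a median of -0.51 over 17 members (adjusted p = 0.00111; adjusted p = 0.472 with an estimated correlation), 3 of them lower when adjusted over the list alone, with *Lyz2* at 0.29 ± 0.35, *Il1b* at -0.08 ± 0.36 and *Ly6c2*, a surface protein of inflammatory monocytes, at -0.91 ± 0.19. Mast cell, eosinophil and basophil genes had a median of -0.22 over 13 members (adjusted p = 0.0076; adjusted p = 0.350 with an estimated correlation), *Alox15* called and 4 lower when adjusted over the list alone, and this was the 1 list that fry called by direction (adjusted p = 0.0112). Gut homing and retinoic acid genes had a median of -0.27 over 17 members (adjusted p = 0.0137; adjusted p = 0.350 with an estimated correlation), with the integrin chain *Itgb7* at -0.28 ± 0.14. The monocyte list was not called without Δchat replicate 3 (adjusted p = 0.0594) or WT replicate 1 (0.0518), nor the mast cell list without Δchat replicate 3 (0.0594); over their 13 alternatives other than the estimated correlation, the lowest adjusted p values were 1.9e-04 and 0.00117. The median of the mast cell list was -0.38, -0.58 and -0.11 without Δchat replicates 1, 2 and 3, and -0.41 and -0.14 without WT replicates 2 and 4. That of inflammatory genes was -0.38 without Δchat replicate 2 and -0.13 without Δchat replicate 4, that of monocytes -0.29 without WT replicate 1, and that of gut homing genes -0.13 without WT replicate 2. With a stromal covariate the median was -0.52 for the mast cell list and -0.27 for monocytes. With the replicate number as a block it was -0.57 for the mast cell list. With the epithelial covariate it was -0.13 for inflammatory genes.

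Of the lymphocyte lists in ileum, 3 were called lower by camera, and Th17, cytotoxic and B cell genes were not called. Regulatory T cell genes had a median of -0.25 over 20 members, 16 lower and 4 higher (camera adjusted p = 0.0137, or 0.902 with an estimated correlation). Among the most abundant, *Ctla4*, an inhibitory receptor, had a value of -0.49 ± 0.19. *Entpd1* did not fall, with libraries at 217 to 352 CPM in Δchat and 240 to 266 CPM in WT, scaled over the 16 libraries. Nor did *Nrp1*, at 170 to 290 and 146 to 203 CPM. T cell genes had a median of -0.17 over 19 members (adjusted p = 0.0376; adjusted p = 0.902 with an estimated correlation), with *Cd28*, a costimulatory receptor, at -0.54 ± 0.14. Type 2 lymphocyte genes had a median of -0.46 over 14 members, 11 lower and 3 higher (adjusted p = 0.0376, or 0.902 with an estimated correlation). The interleukin receptor *Il17rb* had a value of -0.74 ± 0.44. Another, *Il9r*, lay at 33.4 to 56.0 CPM in Δchat and 25.8 to 46.5 CPM in WT, scaled over the 16 libraries. Dendritic cell genes had a median of -0.11 over 24 members (adjusted p = 0.00542; adjusted p = 0.552 with an estimated correlation). Immediate early and heat shock genes had a median of -0.18 over 30 members (adjusted p = 0.00542; adjusted p = 0.880 with an estimated correlation), with 2 higher and 4 lower when adjusted over the list alone, and *Fosb*, a stimulus-induced transcription factor, at -0.86 ± 0.14 (adjusted p = 0.0943). With the epithelial score as a covariate, 8 lists were called in place of 13, and these 5 lists were not among them. The call of regulatory T cells also ended without Δchat replicates 1, 3 or 4 or WT replicate 2, that of T cells without Δchat replicate 3 or WT replicates 2 or 4, that of type 2 lymphocytes without Δchat replicates 1, 3 or 4 or WT replicates 1 or 2, and that of immediate early genes without Δchat replicate 1, with adjusted p values of up to 0.180, 0.574, 0.425 and 0.105. The median of regulatory T cells was -0.63 without Δchat replicate 2 and -0.14 without Δchat replicate 3. That of T cells was -0.09 without Δchat replicate 3 and -0.08 without WT replicate 2. That of type 2 lymphocytes was -0.86 without Δchat replicate 2, -0.26 without Δchat replicate 4 and -0.19 without WT replicate 2, and that of dendritic cells -0.27 without Δchat replicate 2. With a stromal covariate the medians were -0.50 for regulatory T cells, -0.34 for T cells, -0.74 for type 2 lymphocytes and -0.20 for dendritic cells, and with the epithelial covariate the last was -0.20.

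Epithelial transcripts in ileum had a median of 0.79 over 22 members (camera adjusted p = 0.00542; adjusted p = 0.902 with an estimated correlation), with *Krt8* at 0.80 ± 0.91, and ileal and Paneth genes one of 0.93 over 18 members (adjusted p = 0.00489; adjusted p = 0.902 with an estimated correlation), with *Lyz1*, Paneth cell lysozyme, at 1.05 ± 0.77. Without Δchat replicate 4 the medians were 0.41 and 0.38, with neither list called (adjusted p = 0.159 and 0.0558). Without WT replicate 1 that of ileal and Paneth genes was 1.41. The call of the general list also ended without Δchat replicate 1 (adjusted p = 0.0699), WT replicate 3 (0.0840) or WT replicate 4 (0.151), and both calls ended with the epithelial score as a covariate (medians -0.0672 and 0.18, adjusted p = 0.964 and 0.181). The stromal list had a median of -0.48 (adjusted p = 0.0764), with a mean of 7.42 ± 0.27 in ileum WT and 6.87 ± 0.64 in ileum Δchat over the 16 libraries. The 17 lists not called had adjusted p values from 0.0764 to 0.989 and medians from -0.48 to 0.35; for B cell genes the median of 0.32 and the test, which pointed down, differed in sign. Of the 13 lists called, 0 passed with an estimated correlation, fry called 1 by direction and 12 in either direction, and 5 lists reached the smallest exact permutation p of 0.0286 per library, with 0 past the threshold after adjustment. The exocrine pancreas list had 2 tested genes in ileum, *Clps* at 0.13 ± 1.04 and *Cela1* at -0.30 ± 0.38, and the 4 tested sex-linked genes had medians of -0.08 in colon and 0.11 in ileum with none called.

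**Figure D4:**
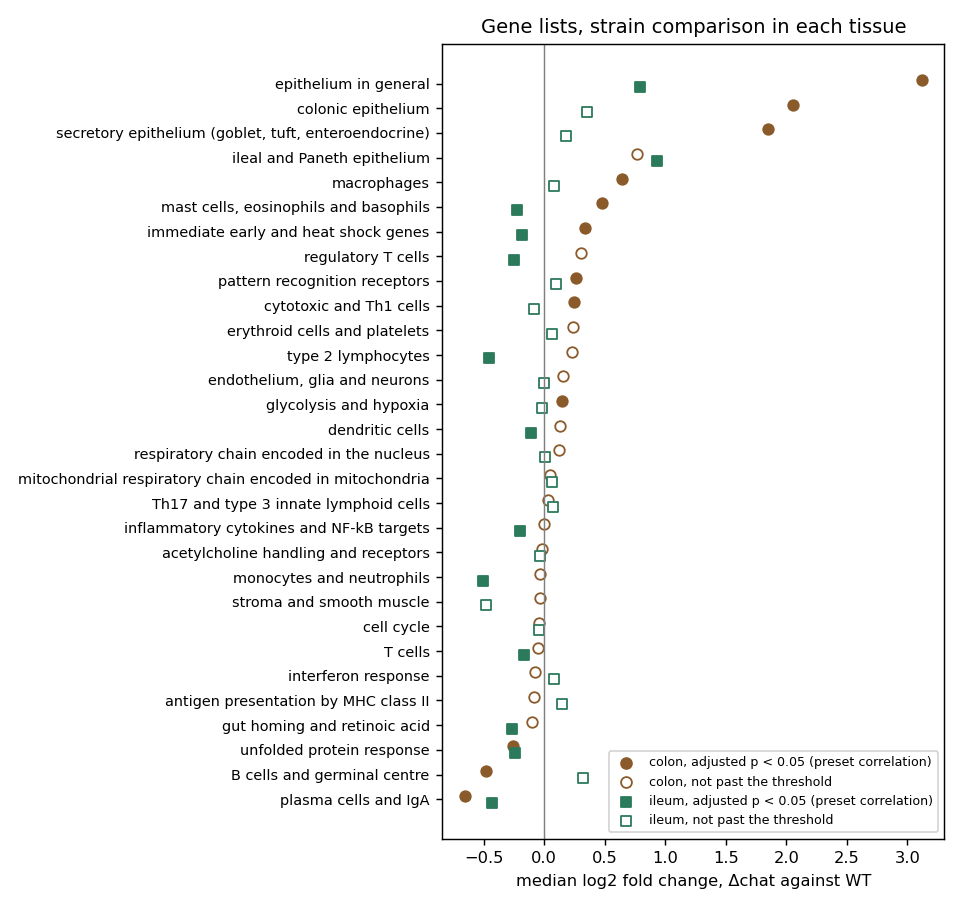
Median log2 fold change (Δchat against WT) of the 30 tested gene lists in colon (circles) and ileum (squares), with filled symbols for lists past the threshold by camera with the preset correlation. Plasma cell and unfolded protein response genes lie below 0 in both tissues, and none of the filled symbols remains past the threshold with an estimated correlation.

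Whether the strain acted differently in ileum and in colon was tested on the 16 libraries together. The effect on *Alox15*, *Il1a*, *Wnt11* and *Mmp25* was lower in ileum than in colon, and so was that on *Mmp9*, a gelatinase, on *Retnlg*, a resistin-like protein of neutrophils, on *Serpinb2*, an inhibitor of plasminogen activators, on *Rab44* and on *Alox5ap*. With the mouse as a block, *Wnt11* alone of these genes was still called, and the others had adjusted p values from 0.144 to 0.318. The effect on B cell and plasma cell genes was higher in ileum than in colon as lists (adjusted p = 0.00118 and 0.00314 by camera; adjusted p = 0.608 and 0.607 with an estimated correlation).

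Of 15198 genes, 9 passed, all with a lower value in ileum. The differences of log2 fold changes were -3.92 ± 0.56 for *Alox15*, -3.75 ± 0.53 for *Serpinb2* and -1.87 ± 0.25 for *Wnt11* (adjusted p = 0.0269 each), -1.79 ± 0.27 for *Mmp25* (0.0293), -2.37 ± 0.36 for *Il1a* (0.0325), -3.67 ± 0.58 for *Rab44* and -1.10 ± 0.18 for *Alox5ap* (0.0348 each), -1.95 ± 0.32 for *Mmp9* (0.0388) and -3.45 ± 0.57 for *Retnlg* (0.0438). *Serpinb2* stood at 3.79 ± 1.21 CPM in colon WT, 8.03 ± 2.61 in colon Δchat, 7.73 ± 3.33 in ileum WT and 1.23 ± 0.41 in ileum Δchat. *Alox5ap* stood at 22.0 ± 2.33, 37.7 ± 3.77, 24.001 ± 2.05 and 19.2 ± 3.66 CPM in the same order, and *Mmp9* at 6.39 ± 1.02, 8.33 ± 1.90, 85.8 ± 15.4 and 29.0 ± 8.92 CPM. For *Retnla* the difference was -3.04 ± 0.68 and did not pass (adjusted p = 0.257).

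Both tissues came from the same mice, and with the mouse as a block 3 genes passed. These were *Tnfrsf9*, a costimulatory receptor (-1.53 ± 0.12, adjusted p = 0.00836), the light chain variable segment *Igkv1-135* (-2.54 ± 0.23, adjusted p = 0.0124) and *Wnt11* (-1.90 ± 0.20, adjusted p = 0.0257), the first and second of which were named after their values were seen. The blocked values of the other 8 were -4.04 for *Alox15* (adjusted p = 0.188), -3.70 for *Serpinb2* (0.169), -1.76 for *Mmp25* (0.151), -2.39 for *Il1a* (0.211), -3.65 for *Rab44* (0.211), -1.12 for *Alox5ap* (0.144), -1.96 for *Mmp9* (0.188) and -3.47 for *Retnlg* (0.318). Over all 18 alternatives the adjusted p of *Wnt11* ran from 7.6e-09 to 0.234 and that of *Mmp9* from 2.4e-06 to 0.322. An unadjusted p below 0.05 was reached by 1174 genes where 759.9 would be by chance; DESeq2 called 58 genes and limma-voom 12. The count was 18 without Δchat mouse 2, 11 without WT mouse 4 and 0 without any 1 of the other 6 mice.

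By camera, 17 of 30 lists differed between the tissues, 2 upward and 15 downward, and 0 passed with an estimated correlation, where their adjusted p values ran from 0.320 to 0.608; fry called 0 by direction and 4 in either direction. B cell genes had a median difference of 0.88 (adjusted p = 0.00118; adjusted p = 0.608 with an estimated correlation), higher in 26 of 26 members, and plasma cell genes one of 0.40 (adjusted p = 0.00314; adjusted p = 0.607 with an estimated correlation). With a stromal covariate these medians were 0.37 and 0.22, and that of plasma cells was 0.25 with immunoglobulin genes left out. The ileum Δchat libraries stood apart on the B cell list, at 6.15 and 5.82 in replicates 1 and 4 and at 4.27 and 4.11 in replicates 2 and 3. Ileum WT libraries lay between 4.74 and 5.83, and the strains did not differ there per library (exact p = 0.914). Immediate early and heat shock genes had a median of -0.38 (adjusted p = 5.1e-09; adjusted p = 0.453 with an estimated correlation), 11 of 30 lower when adjusted over the list alone. Mast cell, eosinophil and basophil genes had one of -0.62 (adjusted p = 1.5e-05; adjusted p = 0.320 with an estimated correlation), inflammatory genes one of -0.22 (adjusted p = 2.6e-05; adjusted p = 0.453 with an estimated correlation) and macrophage genes one of -0.43 (adjusted p = 3.3e-04; adjusted p = 0.607 with an estimated correlation). With the epithelial covariate the last 2 were -0.35 and -0.75. Epithelial genes moved with them, with a median of -2.11 for the general list (adjusted p = 4.5e-04; adjusted p = 0.607 with an estimated correlation), whose call ended without the colon library of Δchat replicate 3 (-0.32) and with the epithelial covariate (0.00351), and whose median was -1.35 with the mouse as a block. The 13 lists not called had adjusted p values from 0.0668 to 0.764.

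The comparison of ileum with colon within each strain gives the regional differences on which the strain effects lie. In mice with WT *B. breve*, the lists of T cells, cytotoxic cells, macrophages, plasma cells and interferon-induced genes were higher in ileum by camera and that of B cells lower, with adjusted p values from 0.2004 to 0.283 with an estimated correlation. *Gzma*, a granule protease of cytotoxic lymphocytes, rose 11.0-fold in ileum, and *Ccr9*, the receptor that directs lymphocytes to the small intestine, rose 7.74-fold. The homeobox genes *Hoxa11* and *Pitx1*, which mark the hindgut, were nearly confined to colon in both strains.

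With WT *B. breve*, 4380 of 15198 genes differed, 2079 higher and 2301 lower in ileum. *Gzma* had a log2 fold change of 3.45 ± 0.19 (adjusted p = 1.9e-07), from 3.42 ± 0.635 to 37.4 ± 6.51 CPM. *Mmp9* had one of 3.75 ± 0.24 (adjusted p = 1.3e-06), *C6*, a complement component, 6.31 ± 0.43 (adjusted p = 1.9e-06), *Ccr9* 2.95 ± 0.22 (adjusted p = 4.3e-06), *Ffar2*, a receptor for short-chain fatty acids, 2.59 ± 0.21 (adjusted p = 6.5e-06) and *Prdm1*, the regulator of plasma cell fate, 1.13 ± 0.10 (adjusted p = 1.5e-05). *Hoxa11* stood at 6.77 ± 2.28 CPM in colon and 0.0281 ± 0.0562 CPM in ileum (adjusted p = 4.0e-05), and *Pitx1* at 19.5 ± 8.93 and 0.736 ± 0.268 CPM (-4.73 ± 0.48, adjusted p = 6.4e-05). *Chrm2* rose in ileum (2.19 ± 0.34, adjusted p = 6.5e-04). *Chrna10* had a value of 1.33 ± 0.41 (adjusted p = 0.0266), *Chrne* one of 0.92 ± 0.29 (adjusted p = 0.0299) and *Chrna2* one of -0.72 ± 0.24 (adjusted p = 0.0359). The calls of *Chrne* and *Chrna2* ended with the mouse as a block (adjusted p = 0.0833 and 0.0626) and without WT mouse 1, 2 or 4 (up to 0.154 and 0.223), while the acetylcholine list did not pass (adjusted p = 0.233).

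With Δchat *B. breve*, 2028 genes differed, 1263 higher and 765 lower in ileum. *Gzma* (3.71 ± 0.19, adjusted p = 9.5e-08), *Ccr9* (2.94 ± 0.22, adjusted p = 6.4e-06) and *C6* (5.99 ± 0.44, adjusted p = 6.4e-06) rose again. *Zbp1*, an interferon-induced sensor of nucleic acids, rose by 1.44 ± 0.13 (adjusted p = 4.5e-05). *Wnt11* was lower in ileum than in colon (-1.59 ± 0.18, adjusted p = 2.2e-04) in these mice, while its value with WT *B. breve* was 0.28 ± 0.18 (adjusted p = 0.261). *Chrm2* had a value of 1.37 ± 0.32 (adjusted p = 0.0118), and *Bche*, which breaks down choline esters, one of -2.53 ± 0.61 (adjusted p = 0.0133). *Chrm2* was not past the threshold without Δchat mouse 2 (adjusted p = 0.0800) or 3 (0.0649), and *Bche* was not without Δchat mouse 3 (0.0752) or with a stromal covariate (-1.35, 0.345). The 2 comparisons shared 1411 called genes of 4997 called in either, and 1405 of these had the same sign, 979 higher in both where 172.8 would be shared by chance and 426 lower in both where 115.8 would be.

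With the mouse as a block, 3900 genes passed in WT and 1875 in Δchat. An unadjusted p below 0.05 was reached by 6213 and 4367 genes, and DESeq2 called 4961 and 2769. The WT count fell to 1719 without WT mouse 1, 2704 without WT mouse 2 and 2082 without WT mouse 4, and the Δchat count to 1149 without Δchat mouse 2; the share of called genes that were higher in ileum with WT was 47.5%, and 59.5% and 60.7% without WT mouse 1 or 4. With Δchat that share was 62.3%, and was 50.7% with the stromal covariate (750 higher and 730 lower) and 54.2% without Δchat mouse 3 (875 and 739).

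Interferon response genes rose in ileum in 28 of 30 members in each strain, with medians of 0.93 with WT (camera adjusted p = 1.5e-15; adjusted p = 0.261 with an estimated correlation) and 1.0045 with Δchat (adjusted p = 4.3e-23; adjusted p = 0.143 with an estimated correlation). The chemokine *Cxcl10* had values of 2.09 ± 0.24 and 2.30 ± 0.24. The counts of members that follow are of those called, not of all that lay above or below 0. Of T cell genes, 13 of 19 members were called higher in each strain and 1 lower in WT (medians 0.87 and 0.89, camera adjusted p = 4.9e-07 and 5.1e-09, or 0.283 and 0.323 with an estimated correlation). Of cytotoxic and Th1 genes, 14 and 12 of 20 members were called higher, with medians of 1.14 and 0.90 (camera adjusted p = 2.9e-10 and 5.8e-10, or 0.2004 and 0.143 with an estimated correlation). Of macrophage genes, 15 and 13 of 22 members were called higher (medians 1.44 and 1.06, camera adjusted p = 1.9e-08 and 1.4e-05, or 0.283 and 0.450 with an estimated correlation), with *Timd4*, a receptor of resident macrophages, at 2.14 ± 0.28 and 1.53 ± 0.28. Of plasma cell genes, 15 and 19 of 27 members were called higher (medians 0.56 and 0.94, camera adjusted p = 4.0e-06 and 1.4e-12, or 0.283 and 0.224 with an estimated correlation), with *Igha* at 1.12 ± 0.25 and 1.74 ± 0.26. Of B cell genes, 19 and 2 of 26 members were called lower (medians -1.53 and -0.76, camera adjusted p = 9.8e-08 and 7.6e-05, or 0.283 and 0.450 with an estimated correlation), with the B cell factor *Ebf1* at -1.25 ± 0.22 and -0.77 ± 0.21. With a stromal covariate the medians of B cells were -1.94 and -1.55, and that of T cells with Δchat was 0.51. The call of *Ebf1* with Δchat ended without Δchat mouse 2 (adjusted p = 0.133).

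Of ileal and Paneth cell genes, 13 and 12 of 21 members were called higher (camera adjusted p = 3.6e-05 and 1.4e-08, or 0.283 and 0.317 with an estimated correlation). Of colonic epithelial genes, 4 and 9 of 16 members were called lower and 2 and 0 higher (camera adjusted p = 0.0416 and 2.4e-05, or 0.573 and 0.361 with an estimated correlation). With WT that list's call was lost with the mouse as a block (adjusted p = 0.0613) and with the stromal covariate (0.153). With Δchat its median ran from -2.89 to -1.28 over the alternatives. Of stromal genes, 4 and 6 of 20 members were called lower, with medians of -0.59 and -0.85 (camera adjusted p = 0.0277 and 8.5e-07, or 0.573 and 0.361 with an estimated correlation). In all, 21 lists were called with WT, 18 of them up, and 20 with Δchat, 15 of them up; 0 passed with an estimated correlation, where the adjusted p values ran from 0.2004 to 0.573 and from 0.143 to 0.598, and fry called 20 and 15 lists by direction. The lists not called had camera adjusted p values from 0.0948 to 0.737 with WT and from 0.0589 to 0.981 with Δchat.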

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

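Of the tests given here, those of dilution, macrophage share, eosinophils, neutrophils, peritoneal macrophages, time of day and tissue handling were chosen after the results were seen, and the others before. In 110 groups of 4 libraries, 13 held a library far from the other 3 by Dixon's criterion, where chance flags about 1 in 20 groups, or 5.5 here.

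Values per library are means of log2 CPM for lists and CPM for genes. In colon Δchat replicate 3, the epithelial list stood at 7.39 (others 3.83 to 4.12), the colonic epithelium list at 4.93 (1.60 to 2.07), the secretory epithelium list at 4.42 (2.14 to 2.50) and the cytotoxic and Th1 list at 3.41 (3.67 to 3.72). In colon Δchat replicate 4, the list of mast cells, eosinophils and basophils stood at 1.19 (2.10 to 2.28) and *Mzb1* at 46.8 CPM (60.6 to 61.8). In colon Δchat replicate 1, the unfolded protein response list stood at 7.08 (7.28 to 7.31). In ileum Δchat, the regulatory T cell list stood at 5.66 in replicate 2 (4.65 to 4.75), *Wnt11* at 3.05 CPM in replicate 1 (4.61 to 4.76) and *Basp1* at 42.1 CPM in replicate 4 (50.6 to 51.6). In ileum WT, the plasma cell list stood at 7.87 in replicate 2 (7.31 to 7.36), and replicate 4 had 10.8 CPM of *Wnt11* (13.963 to 14.1) and 18.2 CPM of *Ciart* (22.0 to 22.7).

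The strain effect differed between ileum and colon, by a test of the difference itself, for 9 genes. The differences, ileum minus colon on the log2 scale, were -3.92 for *Alox15*, -3.75 for *Serpinb2*, -3.67 for *Rab44*, -3.45 for *Retnlg*, -2.37 for *Il1a*, -1.95 for *Mmp9*, -1.87 for *Wnt11*, -1.79 for *Mmp25* and -1.10 for *Alox5ap*. With the mouse as a block, *Wnt11* was still called and the other 8 were not (adjusted p = 0.144 to 0.318). Of 17 lists called by camera with the preset correlation, 0 were with an estimated one (adjusted p = 0.320 to 0.608), and that of endothelium, glia and neurons was lost with the mouse as a block (adjusted p = 0.0526). Among them, B cells (0.88) and plasma cells (0.40) had a higher median difference. The medians were -2.58 for secretory, -2.11 for general and -1.78 for colonic epithelium, -0.62 for mast cells, eosinophils and basophils, -0.60 for type 2 lymphocytes, -0.49 for stroma, -0.47 for regulatory T cells, -0.43 for macrophages, -0.38 for immediate early and heat shock genes, -0.30 for dendritic cells, -0.24 for cytotoxic cells, -0.22 for inflammatory genes, -0.22 for endothelium, glia and neurons, -0.17 for pattern recognition receptors and -0.17 for glycolysis. Without the epithelium-rich colon library, the medians of secretory, general and colonic epithelium were -0.62, -0.32 and -0.15, the last 2 not called. With a stromal covariate, those of B cells and plasma cells were 0.37 and 0.22, and the lists of stroma, of endothelium and of colonic epithelium were not called. Chance could not be excluded for either count: another of the 35 splits of the mice gave as many genes (2 splits, the real one with 9 and the highest other with 18), and 3 splits gave as many lists (17, highest other 20).

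Plasma cell and IgA genes were lower with Δchat *B. breve* in both tissues by camera (adjusted p = 0.488 in colon and 0.472 in ileum with an estimated correlation). The epithelium-rich colon library was argued against as the whole cause, since the median in colon was -0.79 without it. Immunoglobulin counts pulling the normalization were argued against too, since the members that are not immunoglobulin genes had a median of -0.66 with those counts removed. Dilution by cells other than macrophages lowers plasma cell and macrophage genes alike. In colon, the plasma cell mean minus the macrophage mean was 0.695 in Δchat and 1.78 in WT. The difference was -1.08 (exact two-sided permutation p = 0.0286). The plasma cell list alone gave that same p, so it adds no evidence of its own. The macrophage list was not lower, at 5.71 in Δchat and 5.33 in WT (exact p = 0.143), which argues against such dilution as the whole cause in colon. A larger share of macrophages as the whole cause in colon was argued against as well. It lowers the other immune cells alike. The plasma cell mean minus the mean of 8 lists of T cell types, dendritic cells, monocytes and mast cells was 2.58 in colon Δchat and 3.42 in colon WT. The difference was -0.84 (exact p = 0.0286), again the p of the plasma cell list alone. What bears on the explanation is the 8 lists by themselves. They differed by -0.15 for T cells to 0.40 for mast cells, with exact p values of 0.0857 or more. Those of T cells and of monocytes were lower and the rest higher, so none was lowered as plasma cell genes were (-0.70). The B cell list, left out of the 8, fell alike (-0.72 against -0.70 for plasma cells), so the fall was not particular to plasma cells. These tests were run in colon alone. In ileum the means of the plasma cell and macrophage lists were both lower, with differences of -0.42 and -0.25 (exact p = 0.0286 and 0.486), so dilution stays open there. What stays open besides is a change in the number of plasma cells or in their output, and that the 4 mice of each strain differed for another reason, since 24 of 35 splits of the colon libraries called as many lists (12, highest other 17) and chance could not be excluded.

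*Alox15* and *Il1a* fell in ileum with Δchat *B. breve*, and *Mmp25* did not pass (adjusted p = 0.0542). The lists of mast cells and eosinophils, of monocytes and neutrophils and of inflammatory genes were lower by camera (adjusted p = 0.350, 0.472 and 0.472 with an estimated correlation). Carry-over of peritoneal macrophages into the WT libraries stays open: 8 genes of these cells had a median log2 fold change of -0.0183 (exact two-sided permutation p = 0.543), with 4 higher and 4 lower, from -0.93 to 0.90. Fewer eosinophils and fewer neutrophils in the fraction cannot be told apart from a change within cells: 7 eosinophil genes had a median of -0.56 (exact p = 0.0571) and 6 neutrophil genes one of -1.03 (exact p = 0.171), neither past the threshold. Chance was made less likely, but was not excluded, for the count of genes in ileum. Of the 35 splits, 1, the real one, gave as many (3, highest other 0). That is the smallest share 35 splits can give, with no adjustment over the counts tested in this way. For the lists chance stayed open, since 14 splits gave as many (13, highest other 20). The splits were run with the 1 set of choices used throughout, and the count of genes was 0 with RLE size factors, the stricter filter, the block, the epithelial or the stromal covariate, and without Δchat replicates 1 or 4 or WT replicates 1, 2 or 3.

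In ileum with Δchat *B. breve*, heat shock genes had a median of 0.47 (exact p = 0.0857, with overlap of the groups) and immediate early genes one of -0.26. In colon both were above 0, with medians of 0.53 and 0.29 (exact p = 0.2 and 0.114). Collection at another time of day stays open: 9 clock genes that rise and fall with *Ciart* had a median of 0.0651 and went both ways (exact two-sided permutation p = 0.486), while 5 of the opposite phase had one of -0.21, with 3 lower. Longer or harsher handling stays open too. The mean of immediate early genes was 9.08 in Δchat and 9.40 in WT, a difference of -0.31 (exact p = 0.0286), but this restates the pattern and decides nothing about handling. The strain itself stays open, and was not tested apart from the mice that carried it.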

How the results depend on the processing

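The stromal covariate, the removal of the epithelium-rich colon library and the permutation test per library were chosen after the data had been seen, and the other alternatives before. Of the values of named genes under the alternatives, 8911 kept their side of the threshold, 353 lost the call and 56 gained one. Among genes called in the main fit or in the alternative, 0 turned direction. Changes of sign in genes called in neither were not counted. Of the values of called lists, 587 kept direction and call, 143 lost the call and 5 turned direction. With an estimated correlation, 0 lists were called in colon, ileum, the difference between tissues and both tissue comparisons, and 0 in colon and 0 in ileum by exact permutation per library. Genes called in colon (1) numbered 313 with DESeq2, 2 with the epithelial covariate, 0 with the replicate number as a block, 10 in the fit over 16 libraries and from 0 to 3 with each library left out. That block, in colon and in ileum, groups mice of both strains that the design does not pair. The count was 0 without Δchat replicate 1, WT replicate 2 or WT replicate 3, 2 without Δchat replicate 3 or WT replicate 1 and 3 without WT replicate 4. Genes called in ileum (3) numbered 374 with DESeq2, 164 with limma-voom, 42 in the fit over 16 libraries, 5 with no filter, 0 with RLE size factors, the stricter filter, the block, the epithelial or the stromal covariate, and from 0 to 247 with each library left out. The highest count came without Δchat replicate 3; it was 7 without Δchat replicate 2, 11 without WT replicate 4 and 0 without each other library. For the difference between tissues (9), 58 were called with DESeq2, 5 with the stromal covariate, 3 with the mouse as a block, and from 0 to 18 with each mouse left out, 18 without Δchat mouse 2, 11 without WT mouse 4 and 0 without each other mouse. Ileum against colon gave from 1719 to 4950 genes in WT (main 4380; 1719 without WT mouse 1, 2704 without WT mouse 2, 2082 without WT mouse 4) and from 1149 to 1838 in Δchat (main 2028; 1149 without Δchat mouse 2) with each mouse left out. Lists called in ileum numbered 8 with the epithelial covariate, in place of 13, and those of the Δchat tissue comparison 13 with the stromal covariate, in place of 20. Lists whose test turned direction were those that the covariate itself measures or resembles: with the epithelial covariate, epithelium in colon (median 0.0225, its sign kept), colonic epithelium in colon (median -0.21) and epithelium in ileum (-0.0672); with the stromal covariate, stroma in the WT tissue comparison (median -0.0407, its sign kept) and in the Δchat one (0.0852). For the other changes of count the cause was not tested. By camera with the preset correlation, 5 of 12 lists in colon (plasma cells, unfolded protein response, macrophages, immediate early and heat shock genes, pattern recognition receptors), 4 of 13 in ileum (plasma cells, unfolded protein response, inflammatory genes, gut homing) and 13 of 17 in the difference between tissues kept their call under the alternatives run that way, 13 in colon and in ileum and 6 in the difference between tissues; by direction, fry called 1 list in colon, 1 in ileum and 0 in the difference. Unadjusted p values under 0.05 numbered 1951 in colon, 1581 in ileum and 1174 in the difference between tissues by edgeR. In simulated data without correlation between genes, genes changed 2-fold were recovered in 62.2% of cases in colon and 79.4% in ileum, which may be more than in the real libraries.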

Other observations

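Of the tests given here, those of immunoglobulin shares and the genes named from single lists were chosen after the values were seen, and those of variable gene pairing, of the likeness of the tissues and of other splits before. The effective number of heavy chain variable genes was 40.8 ± 2.49 in colon WT and 28.8 ± 4.13 in colon Δchat (n = 4 libraries each), and 43.1 ± 3.99 and 32.8 ± 4.96 in ileum (exact two-sided permutation p = 0.0286 in each tissue, Benjamini-Hochberg 0.1 over 14 measures, which does not pass). The tissues of a mouse are not independent here. Colon and ileum of a mouse shared their variable genes. Over 75 variable genes, the mean correlation between the tissues of a mouse was 0.564 (0.320 to 0.792) and that with other mice of the strain 0.0487 (-0.208 to 0.294), across genes, which are not independent replicates. For 8 of 8 mice the own partner was highest, and a one-sided exact permutation test over 576 pairings gave p = 0.00174, the smallest it can give, which fits libraries of the same number coming from the same mouse. Over the whole transcriptome the same pairs correlated at 0.22, 0.27, 0.19 and -0.18 with Δchat and at -0.06, 0.07, -0.05 and -0.04 with WT, and 6 of these 8 values lay within the range of other pairs of the strain, from -0.30 to 0.22 with Δchat and from -0.16 to 0.18 with WT.

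Single genes of several lists were called when adjusted over the list alone, and the adjusted p values that follow are of that kind. None of these genes was called over all genes. There the adjusted p by edgeR was 0.241 for *Gcsam* and 0.267 for *Mef2b* in colon, and 0.124 for *Hspa1a* and 0.125 for *Hspa1b* in ileum. Of the dendritic cell list in colon, the plasmacytoid gene *Siglech* (-1.05 ± 0.20) and *Bst2* (-0.74 ± 0.13) were lower with Δchat (adjusted p = 0.00747 each by edgeR). *Bst2* also belongs to the interferon response list and does not mark 1 cell type. Of the same list, 6 members were higher, *Flt3* (0.43 ± 0.10, adjusted p = 0.0139) and *Itgax* (0.58 ± 0.16, adjusted p = 0.0329) among them. The germinal centre genes *Gcsam* (-0.92 ± 0.21) and *Mef2b* (-1.09 ± 0.26) were lower in colon (adjusted p = 0.0156 and 0.0165), and *C1qa*, a complement component of macrophages, was higher (0.80 ± 0.24, adjusted p = 0.0271). In ileum, the heat shock genes *Hspa1a* (1.34 ± 0.25) and *Hspa1b* (1.44 ± 0.27) were higher (adjusted p = 0.00507 each). *Cxcl3*, a neutrophil chemokine (-2.86 ± 0.42, adjusted p = 0.00133), *Ccr3*, the eotaxin receptor of eosinophils (-2.71 ± 0.47, adjusted p = 0.00198), and *Il6* (-1.35 ± 0.27, adjusted p = 0.00853) were lower in ileum. Of the Th17 list in ileum, *Il17a* (-2.34 ± 0.49) and *Ahr* (-0.35 ± 0.08) were lower (adjusted p = 0.0163 each), and *Il17re* (0.96 ± 0.29) was higher (adjusted p = 0.0454). Of the cytotoxic and Th1 list there, *Ifng* (1.22 ± 0.30) and *Tbx21* (0.53 ± 0.12) were higher and *Il12rb2* (-0.73 ± 0.17) lower (adjusted p = 0.0221 each).

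Log2 fold changes of the strain in colon and ileum correlated at 0.383 across 14198 genes, where 5 of 35 splits of the 8 mice gave as high a value and the highest other was 0.520, so that a strain effect shared by the tissues cannot be told apart from differences between mice that reach both tissues.

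Chance could not be excluded for the 1 gene called in colon, since 4 of the 35 splits gave as many and the highest other called 557. That split set Δchat replicates 1 and 2 and WT replicates 1 and 4 against the rest and points to a structure of the samples that crosses the strains; its sides had stromal list means of 7.50 to 8.01 and 8.16 to 8.51. For ileum against colon, chance was unlikely for the genes in WT (4380, highest other 0, as many in 1 split) and in Δchat (2028, highest other 6, as many in 1 split). In each, 1 of 35 splits is the smallest share possible. Chance could not be excluded for the lists, of which 21 were called in WT (highest other 21, as many in 3 splits) and 20 in Δchat (highest other 21, as many in 5 splits). The splits that part all 4 pairs of tissues, the other 7 of 8, called up to 0 genes and 20 lists in either strain.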
